A study of Saposhnikovia divaricata with 9 samples.

How the data were processed

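RNA was sequenced from leaves of Saposhnikovia divaricata, a medicinal herb of the carrot family, in 9 libraries from plants aged 48 days. The series' design text describes an untreated control and cold treatment at 4 °C for 6 h or 48 h, each in triplicate on an Illumina instrument. The labels place the libraries in 3 groups of 3 by the codes C, M and L, with replicate numbers 1 to 3, and tie no code in words to the control or to either length of cold. The codes are therefore used as they stand, and no condition was read from the expression values. The labels do not say whether the replicates came from separate plants, so the p-values measure only the spread between these libraries. Per the labels, RNA was poly(A) RNA from leaves, while the labels' extraction text names an animal tissue and the labels' genome field names a mouse build. Neither can describe these plant samples, and neither was used.

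The values are FPKM (fragment numbers scaled by the length of the cluster and the mapped fragments of the library) per cluster and library, calculated by the authors and named so per the file headers, rounded to 2 decimals. The aligner, the assembler, the counting tool and the annotation are not given in the sources used here. In the table used here the features carry only cluster identifiers, without gene names, descriptions or sequences. No genome or annotation was used. The 32 gene lists fixed before the data were examined (cold regulators, photosynthesis, specialised metabolism, hormones, markers of other tissues and others) therefore could not be matched to clusters and were not run. For the same reason no genomic positions are given.

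The deposited FPKM table lists 63753 clusters, of which 129 are listed at 0 in every library. Of the clusters, 44526 share the parent number 17261 in their identifier and 19227 carry other parent numbers. Clusters with at least 1 FPKM in at least 3 of the 9 libraries were tested, which kept 35314 and left out 28439. FPKM is not a count, so no count model was used. Values were transformed to log2(FPKM + 1). A linear model with the 3 groups was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 with an intensity trend, with 6 residual and 2.88 prior degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method. A cluster was called changed at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. All fold changes are on the log2(FPKM + 1) scale, which understates the change of clusters with low values. An exact 0 in the table can be a failed estimate, so a cluster at 0 is only said to be listed at 0.

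The total number of fragments per library is unknown. Relative depth was read from low values, which move in steps of 1 fragment: the most frequent ratio between a library and C replicate 1 among clusters below 6 FPKM in every library gives the ratio of their depths. The peak was strongest against typical windows within C, with 977 clusters against 81 for C replicate 3, and weaker for the L libraries, with 192 against 41, 120 against 37 and 222 against 46 for replicates 1 to 3. M replicate 3 was also used as the reference, a choice added after the data were seen. The L peaks then held 575, 304 and 717 clusters against 49, 45 and 54. The C peaks were weaker there, with 292, 254 and 334 clusters against 73, 88 and 82. On this reference the mean depth of L was 1.045 times that of C. Different fragment lengths can shift this estimate slightly. Without fragment counts no counting interval can be given for a cluster.

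The naming rule, written before the data were examined, took the clusters with the largest rises and falls among those called whose 3 and 3 values did not overlap and whose mean in the higher group lay in the upper 50% of tested clusters. Because the identifiers have no names in the table used here, only the top rise and the top fall of M against C and of L against C are printed. The part of the rule that required a description, and the part on gene lists, could not be applied.

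Data were simulated for 35314 clusters, 100 of them changed by each fold, with the cluster means of C. The noise was independent and normal, with the spreads as shrunken by limma. The fit was tested on these data. For M against C it recovered 89% of 4-fold and 98% of 8-fold changes with 11 false calls. For L against C it recovered 86% and 96% with 5 false calls. In the real data far more clusters were called, 12.9% for M against C and 40.7% for L against C. The false calls of the simulation therefore do not estimate those among the real calls. The changed clusters were drawn only from those with a mean in C above a fixed level, so recovery among low clusters was not measured. Overlaps between comparisons that share the C libraries were set beside 100 simulations in which no group differed. Exact permutation tests between 3 and 3 libraries were two-sided, and the smallest p they can give is 0.1. No 2 libraries held identical values. Same-numbered replicates of different groups did not deviate together: the correlations of their deviations from the group means ran from -0.06 to 0.031. The numbers were not taken as pairs.

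Alternatives fixed beforehand were a replicate block, quantile normalization, median scaling, no filter and a filter at 5 FPKM, robust variance estimation, pseudocounts of 0.1 and 5, fits of only the 6 libraries compared, no fold threshold, and leaving out each library. A fit of only the clusters of the large parent number, and median scaling without C replicate 2, were added after the data were seen. Plots were drawn with matplotlib 3.10.9.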

Results

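The transcriptome of Saposhnikovia divaricata leaves was profiled in 9 libraries, 3 in each of the groups coded C, M and L. The study compared leaves of untreated plants with leaves of plants kept in the cold for a shorter or a longer time, but the labels do not say which code stands for which condition. Expression is therefore compared between codes. The FPKM values of a library summed to between 863749 and 932785, and between 42138 and 51009 clusters were listed above 0. Relative to C replicate 1, the depth read from the steps of low values was 1.02 ± 0.027 (mean ± SD, n = 3) in C, 1.04 ± 0.071 in M and 1.06 ± 0.09 in L. The values of C include the reference itself, set to 1 by definition, so its SD is not comparable with those of M and L. The clusters are unnamed in the table used here, so the comparisons describe clusters and abundance classes rather than genes of known function.

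The libraries separated by group. The first principal component held 55.0% of the variance and ordered the groups as C, M and L, with scores from -119.9 to -113.3, from -44.4 to -34.2 and from 148.4 to 161.9. The second component, with 18.3%, set M apart from both other groups. Spearman correlations over tested clusters were 0.858 to 0.943 within C, 0.901 to 0.923 within M and 0.863 to 0.892 within L. Between groups they were 0.773 to 0.821 for C with M, 0.732 to 0.766 for M with L and 0.626 to 0.691 for C with L, so every library correlated most with its own group. Within C, replicate 2 lay further from the others, at 0.858 and 0.869, than they lay from each other, at 0.943.

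**Figure D1:**
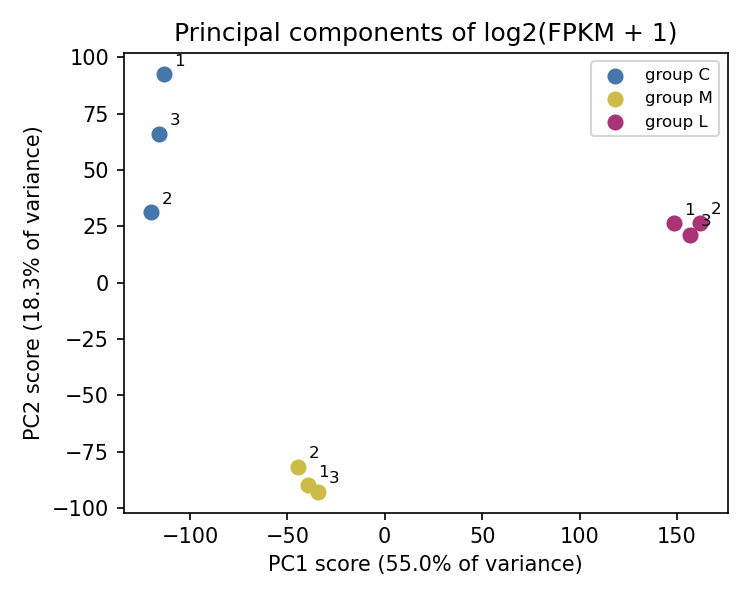
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), with the percent of variance on each axis and 1 point per library labelled by its replicate number. Groups C, M and L form separate clusters along the first component, with M between C and L.

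Group L differed from C and M in how expression was spread over clusters. An average of 13147.7 ± 601.4 clusters reached 5 FPKM in L, against 17554 ± 564.7 in C and 17424 ± 62.0 in M (mean ± SD, n = 3). Every L library lay below every C and M library, and the exact permutation p of 0.1 is the smallest possible with 3 against 3. At 100 FPKM the groups held similar numbers, 1180.3 ± 27.4 clusters in L, 1178.3 ± 50.4 in C and 1212 ± 39.5 in M (exact p = 1 for L against C and 0.3 for L against M). At 1000 FPKM the order was the opposite, with 100.3 ± 7.51 clusters in L, 73.3 ± 4.51 in C and 73 ± 1.73 in M (exact p = 0.1 for both). These numbers depend on scaling: after median scaling L held more clusters than C and M at every threshold, with 16557 ± 195.9 against 16154 ± 132.6 and 15965 ± 49.4 at 5 FPKM, 1904 ± 222.7 against 976.7 ± 87.9 and 987.7 ± 28.1 at 100 FPKM, and 153 ± 28.9 against 59.7 ± 8.33 and 60.7 ± 3.06 at 1000 FPKM. The part of a library taken by its top clusters does not depend on such a factor. The 1000 most abundant clusters of each library took 65.0% ± 2.44 of all FPKM in L, 55.7% ± 1.86 in C and 54.3% ± 0.207 in M (exact p = 0.1 for L against each). The 10 most abundant clusters took a larger part in C, 14.96% ± 1.38, than in M, 11.8% ± 0.195, or L, 11.6% ± 1.06 (exact p = 0.1 for C against each). The values without median scaling belong to 33 such tests, and after Benjamini-Hochberg adjustment over them each exact p of 0.1 became 0.157.

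**Figure D2:**
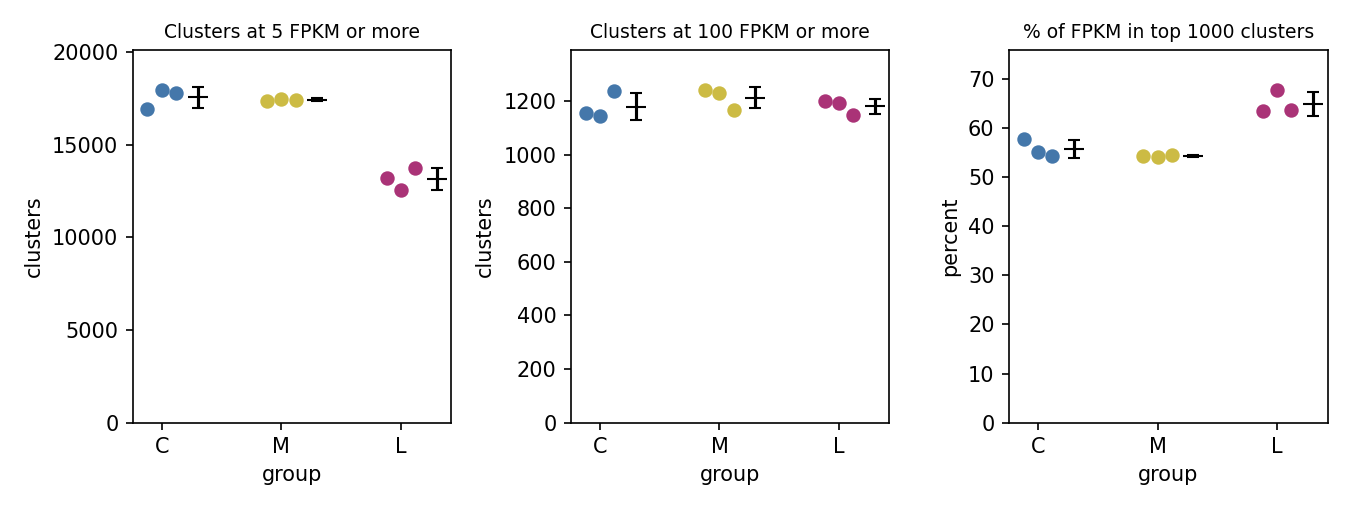
Clusters at 5 FPKM or more, clusters at 100 FPKM or more, and percent of FPKM in the 1000 most abundant clusters (vertical axes from 0) by group, with 1 point per library and the mean and SD of 3 libraries beside them. With FPKM as deposited, L lies below C and M at 5 FPKM (13147.7 against 17554 and 17424) and level with them at 100 FPKM, while median scaling puts it above them at both, and it lies above them in the part taken by the top 1000 clusters (65.0% against 55.7% and 54.3%).

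Comparing M with C, 2883 clusters rose and 1662 fell among 35314 tested, or 12.9% of them (limma, adjusted p below 0.05 and at least 2-fold). The median change was 1.69 on the log2(FPKM + 1) scale among those that rose and -1.45 among those that fell, and 959 rose and 278 fell by at least 4-fold. The clusters that rose took 3.39% ± 0.378 of all FPKM in C and 13.6% ± 0.423 in M (mean ± SD, n = 3), and those that fell took 11.4% ± 0.32 in C and 4.01% ± 0.451 in M. These parts describe clusters selected on the same libraries. Among 1491 clusters with a mean of at least 100 FPKM in C or M, 240 rose, 102 fell and 1149 were not called. Clusters present in every library of a single group were also counted: 32 clusters were listed at 0 in all 3 C libraries and at 5 FPKM or more in all 3 M libraries, and 8 showed the reverse. Mixed splits of these 6 libraries gave at most 2 such clusters. A cluster that separates the groups in this way cannot count in a mixed split, so that number does not estimate what chance would give.

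The largest rise in M against C was that of Cluster-17261.4898, from 1.15 ± 0.16 FPKM in C to 470.4 ± 106.6 in M, a log2 fold change of 7.75 with a standard error of 0.191 (limma, adjusted p = 3.87e-07). Its log2 fold change in M against C was 8.535 with a pseudocount of 0.1 and 6.247 with 5, which the standard error does not cover. The cluster was at 1574 ± 229.9 FPKM in L, higher than in M by 1.75 ± 0.191 (log2, SE, limma adjusted p = 0.000187). The largest fall was that of Cluster-17261.14704, which stood at 217.07, 80.05 and 141.58 FPKM in the C libraries and was listed at 0 in all 3 M and all 3 L libraries (limma, adjusted p = 7.08e-06 for M and 1.28e-06 for L against C). The count of calls depended on single libraries. It was 3078 without C replicate 1 and 5564 without C replicate 2, the library that stood apart.

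Comparing L with C, 3599 clusters rose and 10780 fell, together 40.7% of the 35314 tested (limma, adjusted p below 0.05 and at least 2-fold). The median change was 1.88 among those that rose and -1.61 among those that fell. At least 4-fold changes comprised 1637 rises and 3142 falls. The balance of directions depended on scaling, since the median of all tested clusters lay at -0.563 in this comparison and at -0.031 in M against C. Quantile normalization gave 5328 rises and 5886 falls, and scaling each library to the same median gave 6636 and 5213. Under all 3 scalings 3581 clusters rose and 4839 fell. Without C replicate 2 the counts were 3665 and 10945.

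Among abundant clusters, picked on FPKM as deposited and kept the same under each scaling, rises outnumbered falls. A cluster could enter through the group where it was high, and as deposited more clusters reached 1000 FPKM in L than in C. Of 1754 clusters with a mean of at least 100 FPKM in C or L, 576 rose and 483 fell, against 562 and 483 after quantile normalization and 754 and 236 after median scaling. Of 137 clusters at 1000 FPKM or more, 70 rose and 37 fell, against 62 and 39 after quantile normalization and 78 and 14 after median scaling. The clusters that rose took 6.89% ± 0.638 of all FPKM in C and 46.0% ± 1.53 in L, and those that fell took 43.8% ± 0.901 in C and 12.1% ± 0.432 in L (mean ± SD, n = 3; clusters selected on the same libraries). Between groups, 44 clusters were listed at 0 in every C library and at 5 FPKM or more in every L library, and 28 showed the reverse. Mixed splits gave at most 1, which again does not estimate what chance would give.

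Cluster-17261.4694 had the largest rise in L against C. It stood at 0, 0 and 0.99 FPKM in the C libraries, 200 ± 58.2 in M and 8669 ± 350.8 in L, a log2 fold change of 12.75 with a standard error of 0.3 in L against C (limma, adjusted p = 7.45e-08) and of 5.47 in L against M (limma, adjusted p = 1.47e-05). The size of its rise from C hung on the pseudocount, with 15.254 at 0.1 and 10.673 at 5. The standard error does not cover this. Cluster-17261.29543 had the largest fall, from 429.7 ± 102.2 FPKM in C to 0.853 ± 0.26 in L, a log2 fold change of -7.84 with a standard error of 0.201 (limma, adjusted p = 9.05e-08). This cluster fell by -8.828 with a pseudocount of 0.1 and by -6.189 with 5 (log2). In M it was at 320.6 ± 36.4 FPKM, and its log2 fold change of -0.40 against C did not pass the test (limma, adjusted p = 0.203).

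**Figure D3:**
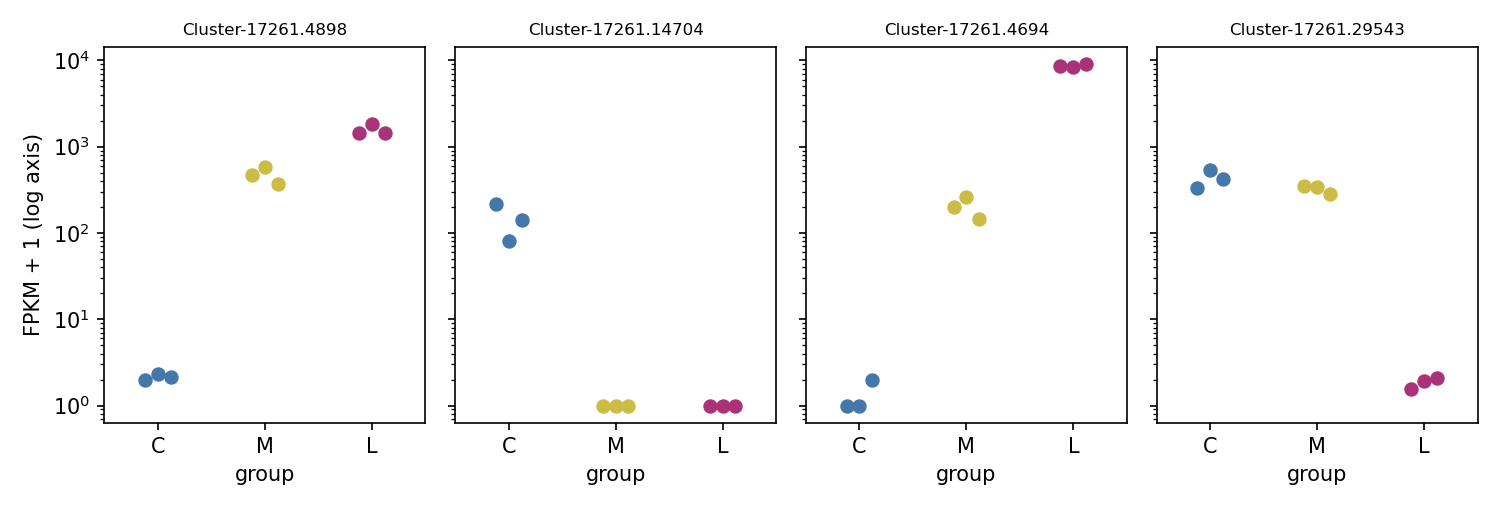
FPKM + 1 on a log axis in the 3 libraries of each group for the clusters with the largest rise and fall in M against C (Cluster-17261.4898 and Cluster-17261.14704) and in L against C (Cluster-17261.4694 and Cluster-17261.29543). Both rising clusters are highest in L; Cluster-17261.14704 is listed at 0 in M and L, and Cluster-17261.29543 is low in L alone.

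Comparing L with M, 2117 clusters rose and 9068 fell, together 31.7% of those tested (limma, adjusted p below 0.05 and at least 2-fold), with the median of all tested clusters at -0.551. Here too the directions depended on scaling: 3967 rose and 4074 fell after quantile normalization, and 5380 rose and 3841 fell after median scaling. Under all 3 scalings 2079 rose and 3226 fell. Of 1627 clusters with a mean of at least 100 FPKM in M or L, 431 rose and 342 fell, against 396 and 353 after quantile normalization and 726 and 145 after median scaling.

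**Figure D4:**
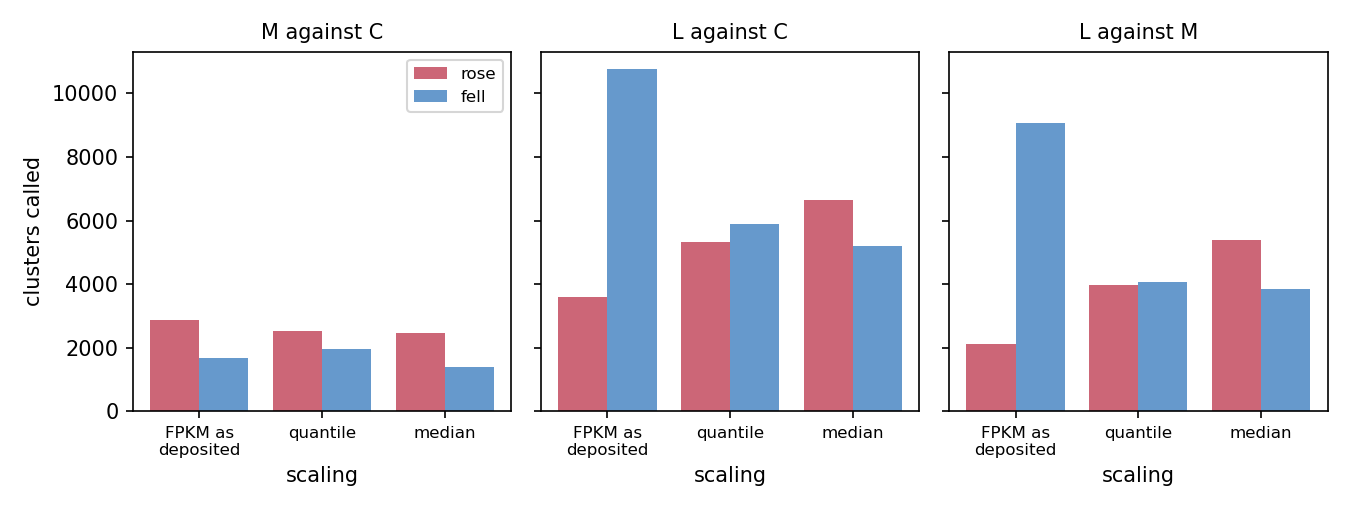
Clusters called as risen or fallen (vertical axis from 0) in each comparison, with FPKM as deposited, after quantile normalization and after median scaling. For L against C the bars change from 3599 rises and 10780 falls as deposited to 5328 and 5886 (quantile) and 6636 and 5213 (median), while in M against C rises outnumber falls throughout.

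The calls of the 3 comparisons were combined into patterns. In the most frequent pattern L differed from both other groups in the same direction while M against C was not called: 1394 clusters were higher and 5915 lower in L. With quantile normalization these were 2616 and 2295 clusters, and with median scaling 3662 and 2093. A further 439 clusters rose in M against C and again in L against M, and 449 fell in both steps (518 and 264 with quantile normalization, 727 and 208 with median scaling). Clusters called higher in M than in both C and L, with no call between C and L, numbered 1034, against 37 lower in M than in both. This excess was smaller but had the same direction with quantile normalization, 616 against 171, and with median scaling, 602 against 129.

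Of the clusters that changed in M against C, 1344 rose and 1488 fell in L against C as well. These were 46.6% of the rises and 89.5% of the falls in M. Independent lists of these sizes would share 294 rises and 507 falls. The balance of shared calls turned with scaling: quantile normalization gave 1499 shared rises and 1344 shared falls (59.5% and 68.6% of the calls in M), and median scaling gave 1541 and 1029 (62.4% and 73.3%). In 100 simulations in which M and L did not differ from C, the mean overlap was 0 in each direction, but at most 2 clusters were called in any of them, so this value does not measure how many shared calls come from the shared C libraries. The log2 fold changes against C correlated across clusters at 0.627, against 0.5 in the simulations, and their covariance was 0.796 against 0.066. Clusters are not independent replicates, and no p-value is attached to this correlation. With 3 C libraries the controls could not be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls.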

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

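The tests of depth, scaling, mixing, swapping and sequence variants in this part were chosen after the results were seen; the comparison with other splits of the libraries was planned. The changes of M and L against C differed in 11185 clusters, tested directly as L against M (limma). Of these calls, 95 clusters had risen in M and fallen in L, both against C, and 2 clusters had fallen in M and risen in L; all 97 were called in L against M. After quantile normalization the numbers of such opposite calls were 56 and 6, and after median scaling 35 and 6.

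The excess of falls over rises in L against C, 10780 against 3599 clusters, was weighed against technical explanations. Lower depth of the L libraries is argued against by the steps of low values, which put the mean depth of L at 1.046 times that of C (1.045 with M replicate 3 as the reference), with single L libraries at 0.977 to 1.157 of C replicate 1; the highest, L replicate 2, had the weakest peak, 120 clusters against 37 in a typical window. A single scaling factor per library cannot be told apart from a change in the clusters as the source of the excess: median scaling, which is such a factor and fixes the median by construction, gave 6636 rises and 5213 falls, and all 4 abundance bins lay below 0. Such a factor would shift clusters of every abundance alike. Clusters with a mean of at least 5 FPKM over all 9 libraries were split by that mean into 4 equal bins. The median log2 ratio of L to C rose from -0.999 in the lowest bin to -0.397 in the highest. The difference of 0.602 ran from 0.354 to 0.895 over the 9 pairs of L and C libraries. A cluster high in L can enter a high bin through its L values, however. The rise with abundance therefore does not decide by itself whether 1 factor could account for it. The part of FPKM in the 1000 most abundant clusters does not depend on such a factor. It was 65.0% ± 2.44 in L and 55.7% ± 1.86 in C (mean ± SD, n = 3). This argues against 1 factor as the only difference between these libraries, but leaves open the balance of rises and falls. FPKM are relative, so it stays open whether moderately expressed clusters fell in amount or only in proportion as abundant clusters rose; a biological difference of group L, whichever condition it codes, was not tested apart from this.

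In C replicate 2, 175 clusters were at 0.1 FPKM or less while both other C libraries had at least 5 FPKM. Such clusters numbered 7 and 3 in C replicates 1 and 3. In reverse, 297 clusters were at 5 FPKM or more in C replicate 2 and at 0.1 FPKM or less in both other C libraries. Those present alone in this sense numbered 120 and 64 in C replicates 1 and 3. The M and L libraries were not part of these counts. RNA of another organism mixed into C replicate 2 would dilute the plant's clusters alike, and taking 5 FPKM to 0.1 FPKM needs a log2 ratio of -5.64. The 15809 other clusters at 5 FPKM or more in both other C libraries had a median ratio of -0.042 (quartiles -0.366 and 0.251). This argues against such mixing into C replicate 2 as the source of the 175 clusters. RNA of another organism in C replicates 1 and 3, but not in C replicate 2, was not tested for them. RNA of another tissue of the plant was not tested for either set. For the 297 clusters present in this library alone among the C libraries, which held 0.707% of its FPKM, RNA of another organism stays open too. Whether these 297 clusters are expressed in M or L was not examined. A swap with an M or L library is argued against by rank correlations: the lowest of C replicate 2 with a C library exceeded its highest with an M or L library by 0.0417, and every M and L library was closest to its own group. Sequence variants of the sampled plants, split over separate clusters, may be a candidate explanation. Of the 175 clusters, 164 carry the large parent number. Of these, 0.61% lay within 5 identifier numbers of a cluster present in C replicate 2 alone among the C libraries. The share was 1.54% of other clusters (Fisher's exact test, two-sided, p = 0.525). This does not decide it, since nothing ties neighbouring numbers to similar sequences, and no biological difference between the C samples is given in the labels.

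In other splits of the same 6 libraries, the real split alone (1 of 10) reached its count in each comparison. The real counts were 4545 for M against C, 14379 for L against C and 11185 for L against M, and the highest of the other splits gave 0, 3 and 0 clusters. Each of the other splits mixes the 2 groups, which puts the difference between them into the spread. Their counts therefore do not estimate the calls to be had by chance. With 10 splits the share cannot fall below 0.1.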

How the results depend on the processing

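No cluster that was called both as reported and under an alternative run here changed direction, and the 4 clusters named in the text kept their direction and call under every alternative run. A reversal needed a call in each direction, and the named clusters were picked for the largest changes, so both results say little. Fewer calls were kept at all: with median scaling 8811 of 14379 stayed in L against C. In L against M 5958 of 11185 stayed, and in M against C 3861 of 4545. The replicate numbers do not mark shared plants or days as far as the labels say; with a replicate block the counts were 4089 for M against C, 14315 for L against C and 10967 for L against M, and for 2 of 9 libraries the deviations from the group mean correlated best, among libraries of the other groups, with one of their own number. Counts that moved by more than 1.5 times did so as follows. For M against C, a filter at 5 FPKM, which tested 19044 clusters, gave 2845 calls (1848 rises, 997 falls) and 904 falls shared with L. A pseudocount of 5, which shrinks the fold of low clusters, gave 1997 calls (1343 and 654) for M against C, 6980 (2177 and 4803) for L against C, 4776 (1314 and 3462) for L against M, and 1304 shared calls (708 and 596). Without the fold threshold there were 2915 falls in M against C and 4403 shared calls, 2687 of them falls. Quantile normalization gave 5886 falls in L against C, and 3967 rises and 4074 falls in L against M. Median scaling gave 6636 rises and 5213 falls in L against C, and 5380 and 3841 in L against M. Median scaling without C replicate 2, added after the data were seen, gave 6483 rises and 5537 falls in L against C. Leaving out each library in turn gave 3078 to 5564 calls in M against C, with 1903 rises (without C replicate 1) to 3334 and 1100 falls (without M replicate 1) to 2230; 13680 to 14610 calls in L against C; and 10299 to 11691 in L against M. Absolute depth is unknown, so changes of clusters near 1 FPKM carry an unknown counting error. The gene list tests planned beforehand, with their alternatives, were not run because the clusters carry no names in the table used here.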

Other observations

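Clusters outside the large parent number made up 19227 of the 63753 listed but held 0.859% to 1.62% of the FPKM of a library. In L replicate 3, 4052 of them reached 1 FPKM, against 2123 and 2194 in L replicates 1 and 2, and they held 1.42% of its FPKM against 0.859% and 0.866%. In the M libraries 4113 to 4781 of them reached 1 FPKM, and in the C libraries 3101 to 3924. Restricting the tests to clusters of the large parent number, an alternative added after the data were seen, gave 4219 calls for M against C, 13890 for L against C and 10711 for L against M.

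Of the 175 clusters near 0 in C replicate 2 alone among the C libraries, 119 were tested. Of these, 0 were called in M against C with limma, and 0 with its robust variant, while 17 had an unadjusted p below 0.05. In L against C, 10 were called (limma, adjusted p below 0.05 and at least 2-fold). Over all tested clusters 12.9% were called in M against C and 40.7% in L against C. The set was picked for 1 C library far from the others, which widens its spread and hinders calls against C. Low counts of calls therefore follow largely from the selection. Over all 175 clusters, 44.2% of the values in the M libraries and 53.5% of those in the L libraries were also at 0.1 FPKM or less.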
